A study of Mus musculus with 11 samples.

How the data were processed

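RNA sequencing was analysed for 11 libraries of mouse colorectal organoids, 5 control and 6 treated with 10 pM NAP for 48 h, grouped and numbered by their titles. Per the labels' protocols, total RNA was enriched for poly(A), fragmented, copied with random hexamers and sequenced on an Illumina instrument. The labels call the libraries biological replicates without saying that they came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical in part. The authors deposited a table of whole-number counts per gene. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.39, aligned with HISAT2 2.2.1 to GRCm39 and counted with featureCounts of Subread 2.0.8. The strand setting, the annotation release and the treatment of reads that match several places are not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain. The authors also deposited a table of FPKM values for the same genes. Each FPKM value equalled the count times a constant divided by gene length, with 1 constant per library at 0.870 to 1.28 times the library's count total; how the authors set it is not given in the sources used here.

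The count table held 47131 genes, 13060 of them at 0 in every library. Of these, 800 carried an identifier without a name and took 0.154 to 0.264% of counts; they stayed in the tests but are not named. Count totals ranged from 16546263 to 21947414 per library. A count of 0 in a library allows up to 0.137 to 0.181 CPM (3 counts over the count total, without the TMM scaling of the CPM values below), for counting error only.

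Genes were kept with edgeR's filterByExpr at its defaults (14840 tested), scaled with TMM and compared, NAP minus control, with the quasi-likelihood test of edgeR 4.0.16 (robust, R 4.3.3) and Benjamini-Hochberg adjustment, with a threshold of 0.05. All 11 libraries entered with no covariate, as the labels give 1 batch. Standard errors are the log2 fold change divided by the square root of the test statistic. CPM values are TMM-scaled, with a prior count of 2 where logged. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The 50 lists (13 of cell type markers and 37 of pathways) were tested with camera (limma 3.58.1, correlation 0.01) where at least 5 members were tested, with camera at an estimated correlation and with fry beside it. Library measures and principal components were compared by two-sided exact permutation over the 462 splits of 11 libraries into 6 and 5, with adjustment over 10 measures. List scores (mean deviation of log2 CPM from the gene's mean over libraries) were not tested in this way.

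Named genes were the 10 largest changes in each direction among called genes with a mean log2 CPM of at least 1, a proper symbol and every NAP library on the same side of the control mean; the 5 smallest p-values in each direction; the 4 members with the smallest p in the direction of each called list and up to 2 in each other list; and Adnp. Coordinates are those of the deposited table. Transcript GC content came from GENCODE M21 (GRCm38) through gene identifiers, as a property with no coordinates, and was found for 84.0% of tested and 88.3% of called genes.

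Alternatives covered other scalings and filters, DESeq2 1.42.0, limma on voom and on log2(FPKM + 1) or log2(FPKM + 0.1), other thresholds, a block for the replicate number and each library left out. Those chosen after seeing the data were controls 2 and 5 left out or added together, GC and length trends removed (lowess per library, span 0.3), 1 surrogate variable (sva 3.50.0), a crypt to colonocyte score as a covariate, and the mitochondrial chromosome left out.

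The procedure was tested on simulated counts for 14840 genes of this comparison, with 200 genes changed. At a log2 change of 1, 25 of 100 changed genes were recovered, and at a log2 change of 2, 74 of 100, with 2 unchanged genes called. With no change, 0 genes and 0 lists were called, and 3 of 3 lists shifted by 0.5 were recovered, or 2 of 3 with an estimated correlation or with fry. Genes were drawn independently of each other in these simulated counts. They therefore do not show how often genes or lists are called by chance when genes move together between libraries.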

Results

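RNA was measured by poly(A)-selected sequencing in mouse colorectal organoids, which are epithelial cultures grown in Matrigel from colon tissue of female C57BL/6J mice aged 6 to 8 weeks. Of the 11 libraries, 6 came from organoids given 10 pM NAP for 48 h and 5 from control organoids. The labels do not spell out what NAP is. They describe the controls as untreated in one place and as given phosphate-buffered saline as vehicle in another. All libraries carry batch label 1. Total gene counts ranged from 16546263 to 21947414 per library, with a mean of 18.3 ± 2.18 M in controls (SD, n = 5) and 18.1 ± 1.51 M after NAP (SD, n = 6; two-sided exact permutation p = 0.818).

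The comparison of NAP with control asked which transcripts differed in level after 48 h of treatment. Duox2, a dual oxidase that makes hydrogen peroxide at mucosal surfaces, rose 4.26-fold, from 71.5 ± 41.0 to 304 ± 112 CPM (gene counts scaled to library size with TMM; mean ± SD, n = 5 controls and 6 NAP libraries here and below). Slc15a1, the intestinal peptide transporter, rose 3.53-fold, from 36.4 ± 22.5 to 128 ± 31.0 CPM. Cbs, the cystathionine beta-synthase of the transsulfuration pathway, was 5.01-fold lower, at 6.23 ± 4.75 CPM against 31.3 ± 15.7 CPM. Rpl7a, a protein of the large ribosomal subunit, was 2.95-fold lower, at 122 ± 21.8 CPM against 358 ± 139 CPM. In all, 315 of 14840 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 156 higher and 159 lower. For 313 of them every NAP library lay on the same side of the control mean, which their selection in these libraries favours.

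Among called genes with a proper symbol and a mean log2 CPM of at least 1, the largest rises were those of Bnip5 (5.15-fold, 12.5 ± 7.11 to 64.3 ± 40.02 CPM) and of Bche, which encodes butyrylcholinesterase (4.79-fold, 3.53 ± 1.25 to 16.95 ± 6.51 CPM). Bche, gene identifier 12038, lies on chromosome 3 from 73543138 to 73615767 of GRCm39, and its log2 fold change was 2.26 (SE 0.33, adjusted p = 0.0343). Duox2, identifier 214593, lies on chromosome 2 from 122109727 to 122129221 and changed by 2.09 on the log2 scale (SE 0.39, adjusted p = 0.0344). Iyd, the iodotyrosine deiodinase, rose 3.57-fold, and Slc6a7, a proline transporter, rose 3.55-fold. Nat8f4 rose 3.49-fold, Slfn4 of the Schlafen family 3.31-fold and Mt4, a metallothionein, 3.24-fold. These 3 genes belong to families with close paralogs, so reads could be shared between copies. TrnW, the mitochondrial tRNA for tryptophan, rose 3.96-fold, but its interval (4950 to 5016 on the mitochondrial chromosome) meets that of ND2 (3914 to 4951), so reads could be shared there too. The smallest p-values among the rises belonged to Trim36, a ubiquitin ligase of the tripartite motif family, Bche, the mitochondrial fatty acid synthase enzyme gene Oxsm, the monocarboxylate transporter gene Slc5a8 and the epiplakin gene Eppk1. Trim36, on chromosome 18 from 46298367 to 46345674, had 19.5 ± 1.87 CPM in controls and 37.2 ± 2.28 CPM after NAP (log2 fold change 0.93, SE 0.13, adjusted p = 0.0343). Slc5a8 rose 2.75-fold to 76.5 ± 14.4 CPM.

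By the same rule the largest fall was that of Nrtn, which encodes the neurotrophic factor neurturin and was 6.52-fold lower, at 2.04 ± 0.94 CPM against 13.4 ± 11.2 CPM in controls. Controls 2 and 5 held 27.9 and 22.8 CPM and the other controls 3.53 to 7.75 CPM, so the size of this fall rests largely on those 2 libraries. Nrtn, identifier 18188, lies on chromosome 17 from 57058323 to 57064548 (log2 fold change −2.71, SE 0.55, adjusted p = 0.0410). Cbs, identifier 12411, lies on the same chromosome from 31831597 to 31856207 (log2 fold change −2.32, SE 0.54, adjusted p = 0.0476). The tubulin polyglutamylase subunit gene Tpgs1 and the LIM-domain gene Wtip were each 3.17-fold lower. The flotillin gene Flot1 was 3.06-fold lower, Cited4 3.03-fold, Tmed1 2.96-fold, the fibulin gene Fbln1 2.93-fold and Sac3d1 2.71-fold. Mri1, Wtip, Rpl7a and Flot1 were among the falls with the smallest p-values. Mri1, an enzyme of methionine salvage, was 2.00-fold lower, at 23.9 ± 2.03 CPM against 47.8 ± 8.89 CPM (adjusted p = 0.0343). Adnp, a gene fixed for reporting in advance, had 3.41 ± 2.78 CPM in controls and 2.00 ± 1.01 CPM after NAP, and did not pass the test (log2 fold change −0.78, SE 0.61, adjusted p = 0.460).

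**Figure D1:**
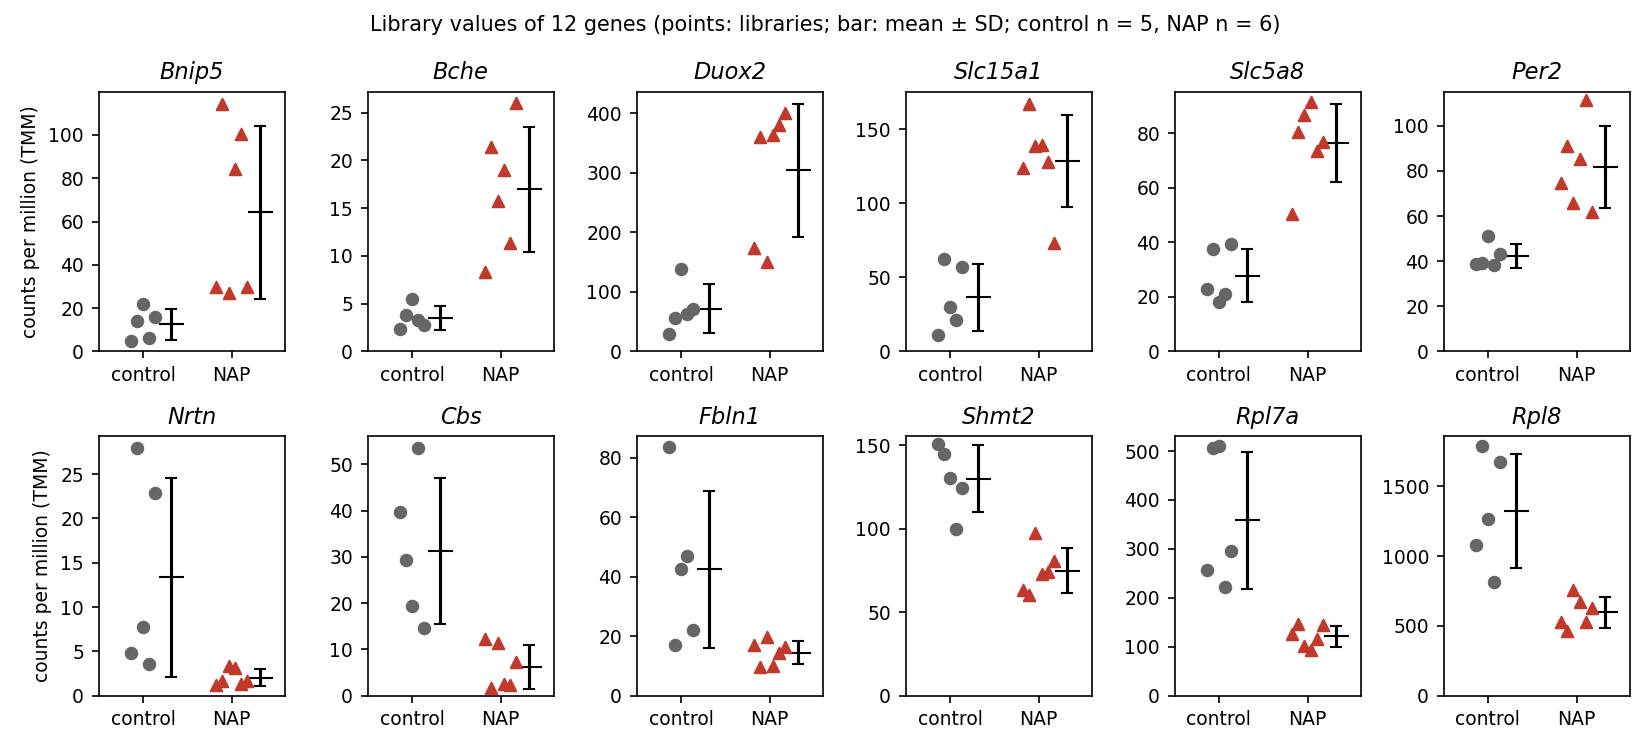
CPM after TMM scaling (vertical axis, linear and starting at 0) of 12 named genes in the 5 control libraries (grey circles) and 6 NAP libraries (red triangles), with the mean ± SD beside each group. For Rpl7a the 6 NAP libraries lie below all 5 controls, around means of 122 and 358 CPM, and for Bche they lie above them.

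The number of calls depended on single libraries: without control 1, 2 or 5 or NAP 2, 4 or 5 in turn edgeR called 0 genes, with 2614 to 3311 genes still at an unadjusted p below 0.05. It called 158 genes without control 3, 436 without control 4, 814 without NAP 1, 790 without NAP 3 and 112 without NAP 6. Of the genes called with all libraries, 311 to 315 were tested in each of the 11 fits and none changed sign. This says little, as they were selected for their difference in these same libraries.

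Among gene lists fixed before the data were examined, 46 of 50 had at least 5 tested members, and camera with its preset correlation of 0.01 called 8 higher and 7 lower than other genes. No list was called with an estimated correlation between genes, where the smallest adjusted p was 0.746, nor by fry's test for a shift on balance in 1 direction, where it was 0.117. Fry's test for change in either direction, which does not compare a list with other genes, called 15 lists, among them apoptosis machinery (adjusted p = 0.0134) and 7 of the lists that camera called. The counts and directions of list members that follow are to be read with that limit.

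Cytosolic ribosomal protein genes had the smallest p of all lists. Of 47 tested members 45 had a negative log2 fold change, the median was −0.58, and 3 passed the test over all genes (Rpl7a, Rpl8 and Rpl15), or 22 adjusted over the list alone, all lower (camera adjusted p = 1.33e-12, but adjusted p = 0.746 with an estimated correlation). Rpl8 fell 2.22-fold, from 1324 ± 408 to 597 ± 109 CPM, and Rpl15 fell 1.67-fold. Rpl11 had 599 ± 146 and 338 ± 53.2 CPM (adjusted p = 0.0504). Genes of this class have many processed pseudogenes, so their counts are uncertain where reads match several copies. All 30 members of the ribosome biogenesis list were negative, with a median of −0.55 and 0 passing over all genes or 3 adjusted over the list alone (camera adjusted p = 1.48e-04, adjusted p = 0.746 with an estimated correlation). Its members with the smallest p were Rrp1, with 136 ± 7.80 and 93.7 ± 13.97 CPM, Bop1, Nop2 and Rrp9, none of which passed over all genes (adjusted p = 0.0566 to 0.0928). The 2 lists rested on different controls. Ribosomal protein scores were 0.665, 0.496 and 0.597 in controls 2, 3 and 5. Controls 1 and 4, at −0.028 and −0.204, lay within the NAP range of −0.591 to 0.239. Ribosome biogenesis scores were 0.798, 0.310 and 1.028 in controls 1, 3 and 4. Controls 2 and 5, at −0.438 and −0.436, lay within the NAP range of −0.676 to 0.306.

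Lists of biosynthesis and of the amino acid response stood lower as well. In the ATF4 list of the integrated stress response, 20 of 23 members were negative, with a median of −0.51 (camera adjusted p = 0.0130, adjusted p = 0.746 with an estimated correlation). Of these, Shmt2, the mitochondrial serine hydroxymethyltransferase, fell 1.74-fold to 74.7 ± 13.5 CPM and Cebpb, a transcription factor gene, fell 2.31-fold to 12.3 ± 3.62 CPM. Adjusted over the list alone, 5 were lower and 1 higher. Psph and Slc3a2, for serine synthesis and amino acid transport, were at log2 fold changes of −0.81 and −0.60 and did not pass over all genes. In the cholesterol synthesis list 17 of 24 members were negative (median −0.37, camera adjusted p = 0.0107, adjusted p = 0.746 with an estimated correlation), 0 passed over all genes and 4 were lower adjusted over the list alone. Mvd had 57.8 ± 10.7 and 25.2 ± 14.1 CPM, and Pmvk, Tm7sf2 and Nsdhl had log2 fold changes of −0.85, −0.64 and −0.64, none past the test over all genes. In the fatty acid and lipid synthesis list 18 of 19 were negative (median −0.40, camera adjusted p = 0.0138, adjusted p = 0.746 with an estimated correlation), with 0 past the test over all genes and 3 lower adjusted over the list alone. Fasn, the fatty acid synthase gene, had 549 ± 134 and 347 ± 60.4 CPM (adjusted p = 0.0770), and Acaca and Srebf1 were at −0.69 and −0.67. Not every NAP library stood lower. The mean score of the cholesterol list was 0.40 in NAP 3 and 0.14 in NAP 6, against 0.15 to 0.27 in controls. That of the fatty acid list was 0.16 in NAP 3 and 0.15 in NAP 6, within the controls at 0.07 to 0.41. In both lists the other NAP libraries lay below every control. For the ATF4 list NAP 1, 3 and 6, at 0.010, 0.113 and 0.035, lay within the controls at 0.009 to 0.654.

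Wnt target and DNA replication genes were called lower, together with a wide spread among controls. All 15 tested Wnt target genes were negative (median −0.80, camera adjusted p = 0.0391, adjusted p = 0.746 with an estimated correlation), and 30 of 32 genes of DNA replication and S phase were (median −0.77, camera adjusted p = 0.0107, adjusted p = 0.819 with an estimated correlation). No member of either list passed, over all genes or adjusted over the list alone. The Wnt target Ccnd1 had 143 ± 144 CPM in controls and 58.0 ± 16.7 CPM after NAP, with a log2 fold change of −1.30 that was −0.53 without control 1, and the replication licensing gene Cdt1 had 35.6 ± 20.0 and 16.5 ± 6.64 CPM. Intestinal stem cell markers, of which 15 of 16 were negative, were not called (median −0.77, camera adjusted p = 0.143), and neither was the mitosis list, with 29 of 30 negative (median −0.50, camera adjusted p = 0.330). A score of colonocyte minus stem cell marker genes stood at −2.57 and −3.47 in controls 1 and 4, at 2.30 and 2.25 in controls 2 and 5, at −0.82 in control 3, and between −0.54 and 1.26 in the NAP libraries. The DNA replication list lost its call without control 1 or 4, and the Wnt list without control 1, 3 or 4 or NAP 4 or 5.

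On the higher side, the circadian clock list had 15 of 17 members positive (median 0.39, camera adjusted p = 8.80e-04, adjusted p = 0.746 with an estimated correlation). Per2, a repressor of the clock loop, rose 1.94-fold, from 42.2 ± 5.33 to 81.7 ± 18.3 CPM, and was the 1 member called over all genes, with 5 higher adjusted over the list alone. Ciart, Bhlhe40 and Nr1d2 were at log2 fold changes of 0.85, 0.91 and 0.80 and did not pass over all genes. In the glycolysis and hypoxia list 21 of 27 were positive (median 0.40, camera adjusted p = 8.80e-04, adjusted p = 0.746 with an estimated correlation). Hk2, a hexokinase gene, rose 1.88-fold, from 133 ± 30.4 to 249 ± 25.5 CPM, and was the 1 call under either adjustment. The hypoxia genes Ndrg1, Ero1a and Bnip3 had log2 fold changes of 1.40, 1.48 and 1.08, none past the test.

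In the actin and brush border list 17 of 25 were positive (median 0.28, camera adjusted p = 0.00704, adjusted p = 0.746 with an estimated correlation), and Eps8, Pls1 and Anks4b, which build or anchor microvilli, rose 2.28-fold, 1.79-fold and 1.77-fold, the 3 calls under either adjustment. Tight and adherens junction genes were positive in 18 of 25 (median 0.23, camera adjusted p = 0.0316, adjusted p = 0.746 with an estimated correlation). None passed over all genes, and 6 were higher and 1 lower adjusted over the list alone. Cdh1, the E-cadherin gene, had 916 ± 158 and 1575 ± 365 CPM (adjusted p = 0.0664), and Ocln, the occludin gene, 123.1 ± 14.6 and 249 ± 94.4 CPM (adjusted p = 0.0540). Markers of small intestinal enterocytes were positive in 10 of 14 (median 0.34, camera adjusted p = 0.0199, adjusted p = 0.746 with an estimated correlation), with 0 past the test over all genes and 2 higher adjusted over the list alone. The bile acid transporter gene Slc10a2 had 16.8 ± 8.50 and 56.4 ± 14.1 CPM (adjusted p = 0.0523), and the sucrase-isomaltase gene Sis 30.3 ± 25.3 and 109 ± 49.0 CPM. The absorptive colonocyte list was called higher (camera adjusted p = 0.0381, adjusted p = 0.819 with an estimated correlation) with its mean at 0.02 but its median at −0.09, and 11 of 25 members positive. Ceacam1 was its 1 call over all genes (1.91-fold, 863 ± 81.7 to 1650 ± 259 CPM), with 2 higher adjusted over the list alone, while Emp1, with 472 ± 229 and 1344 ± 644 CPM (adjusted p = 0.0672), Muc3 and Ms4a8a, at log2 fold changes of 0.58 and 0.67, did not pass over all genes. Xenobiotic metabolism and aryl hydrocarbon receptor genes were positive in 17 of 26 (median 0.26, camera adjusted p = 0.0425, adjusted p = 0.819 with an estimated correlation), with 0 calls over all genes and 3 higher adjusted over the list alone. Tiparp had 26.8 ± 10.2 and 63.9 ± 24.3 CPM (adjusted p = 0.0514). Without control 4 the glycolysis, brush border, junction, enterocyte, colonocyte and xenobiotic lists lost their calls, and without control 1 the last 4 of these and the ATF4 list did. The colonocyte and xenobiotic calls were also lost without control 3, NAP 2 or NAP 4, the xenobiotic call without NAP 5 or NAP 6, the junction call without NAP 1 or NAP 4, and the cholesterol and fatty acid calls without NAP 1.

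**Figure D2:**
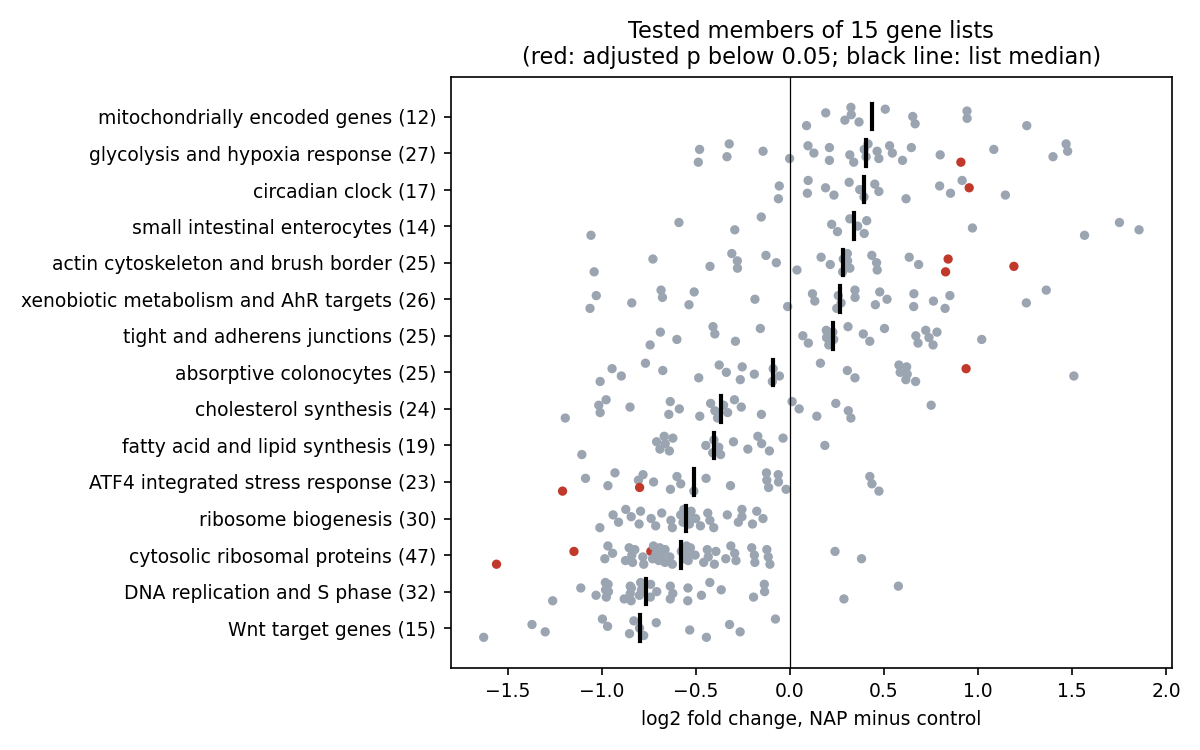
Log2 fold change (NAP minus control, horizontal axis) of every tested member of the 15 gene lists that camera called, with the number of members in brackets, red points for genes with an adjusted p below 0.05 and a black line at each list's median. All 15 Wnt target genes and 45 of 47 cytosolic ribosomal protein genes lie below 0, and all 12 mitochondrially encoded genes lie above it.

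Mitochondrial transcripts took a larger part of the libraries after NAP. Genes of the mitochondrial chromosome held 3.73 ± 0.90% of counts in controls (2.74 to 4.78%) and 6.51 ± 1.25% after NAP (5.17 to 8.08%), higher in 6 of 6 NAP libraries than in any control (two-sided exact permutation p = 0.00433, adjusted p = 0.0216 over 10 library measures). All 12 protein-coding genes tested from that chromosome were positive (median 0.44, camera adjusted p = 0.00293, adjusted p = 0.746 with an estimated correlation), with 0 past the test over all genes or adjusted over the list alone. ND5 had 2259 ± 399 and 3582 ± 896 CPM, and ND2 had 1544 ± 258 and 2193 ± 288 CPM. COX1 held 2.07 ± 0.73% and 3.98 ± 1.23% of counts, over 0.5 of that share, while COX2 had 128 ± 72.1 and 201 ± 166 CPM and COX3 and ATP6 less. Reads could be shared with nuclear copies, which was not tested, so single genes of this chromosome are uncertain. Genes with at least 1 count numbered 23525 ± 2762 in controls and 20813 ± 1073 after NAP (two-sided exact permutation p = 0.0368, adjusted p = 0.0557), and the 10 most abundant genes held 7.14 ± 1.32% and 8.96 ± 1.18% of counts (p = 0.0390 in the same exact test, adjusted p = 0.0557). The libraries also differed in base composition. The rank correlation, across genes, between transcript GC content and a library's deviation from the mean log2 CPM was 0.20 ± 0.13 in controls and −0.20 ± 0.24 after NAP (two-sided exact permutation p = 0.0108, adjusted p = 0.0303). The median GC content was 37.4% in the 12 mitochondrial genes, 45.04% in the called higher genes, 57.2% in the called lower genes and 49.8% over all tested genes. With that trend removed 30 genes were called, 22 higher and 8 lower, and the mitochondrial, ATF4 and xenobiotic lists lost their calls while the NF-kB, heat shock and extracellular matrix lists gained one. The median gene length was 5238 bases in the called higher genes, 2057 in the called lower genes and 3466 over all, and with GC and length trends both removed edgeR called 0 genes, with 2380 at an unadjusted p below 0.05. Of the 315 genes, selected for their difference in these libraries, 278 had a GC value, and in that fit all 278 kept their sign. Their median log2 change in the direction of the call was 0.64 ± 0.44 (SD across genes), from 0.94 ± 0.38.

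The 11 libraries spread mainly along a component that did not follow treatment. The first principal component held 44.2% of the variance and placed controls 1 and 4 at −82.5 and −98.9 and controls 2 and 5 at 60.1 and 64.1, with the NAP libraries from −30.2 to 43.9 (two-sided exact permutation p = 0.439). The second, with 21.6%, separated the groups, at −32.4 ± 28.8 in controls and 27.0 ± 20.8 after NAP (two-sided exact permutation p = 0.00216, the smallest this design can give, adjusted p = 0.0216). It also went with base composition. Controls 2 and 5, at −65.4 and −60.9, had rank correlations with GC content of 0.36 and 0.29. NAP 2 and 5, at 42.8 and 53.5, had −0.25 and −0.32, though NAP 6, with the lowest at −0.54, lay at 22.6. This component therefore does not set treatment apart from the GC trend. Some libraries were close to each other by a chi-square per gene, for which sampling noise gives about 1. Among NAP pairs these were NAP 2 and 5 (14.1), NAP 4 and 5 (22.0) and NAP 2 and 4 (23.6), against a median of 95.7. No fit merged them. A value above 1 does not show separate cultures, so the p-values may count more independent samples than there are. Controls 2 and 5 were the most alike of all control pairs, at 7.99 against a median of 142, and were counted as separate samples. Left out together, they raised the calls to 420 higher and 404 lower, among which 179 of the 315 genes were found again, and added into 1 library they left 0 calls in edgeR, with 3241 genes at an unadjusted p below 0.05 and a median log2 change of the 315 genes, in the direction of their call, of 0.94 ± 0.50 (SD across genes) against 0.96 ± 0.49.

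**Figure D3:**
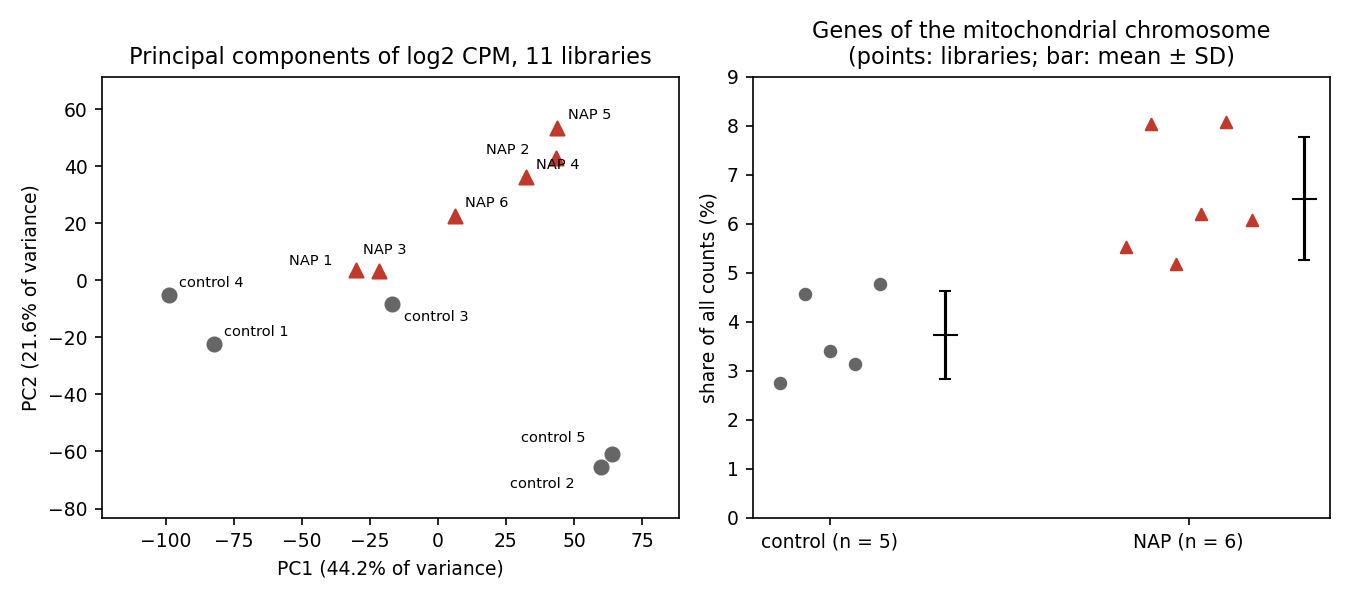
Left, principal components of log2 CPM for the 5 control (grey circles) and 6 NAP (red triangles) libraries, with PC1 at 44.2% and PC2 at 21.6% of the variance. Right, the share of all counts from genes of the mitochondrial chromosome in percent, with the mean ± SD beside the points. The NAP libraries lie from 5.17 to 8.08%, above the controls at 2.74 to 4.78%.

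Of the 46 tested lists 31 were not called by camera, with adjusted p from 0.120 to 0.994, among them the marker lists of other cell types. The camera adjusted p was 0.632 for goblet cells, 0.424 for enteroendocrine cells, 0.371 for tuft cells, 0.371 for deep crypt secretory and Paneth-like cells, 0.369 for fetal-like and regenerative epithelium and 0.371 for squamous or anal epithelium. Of these, fry's test for change in either direction called the fetal-like list alone (adjusted p = 0.0167). Markers of immune cells, endothelium, enteric neurons and glia, and fibroblasts had 3 or 4 tested members each, too few for the list test. Of these, Fbln1 in the fibroblast list was the 1 member called over all genes, with 42.4 ± 26.3 CPM in controls and 14.5 ± 3.98 CPM after NAP. Adjusted over the list alone, 1 immune cell marker was higher as well.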

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

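Of the tests here, the count of splits for called genes, the GC and crypt to colonocyte tests on called genes and lists, the fit with 1 surrogate variable and the GC test on mitochondrial genes were chosen after the result was seen. The GC and crypt to colonocyte tests on called genes replaced earlier ones whose outcome was known: the first GC test used the median change of the called genes, which had been selected for the pattern, and the first axis test used the surrogate variable, whose fit protects the treatment term. The count of splits with a surrogate variable was first run on a part of the splits, which held none of the others with many calls, and then on all 100. In 17 of 348 groups of library values, 1 library stood far from the others of its group, and chance alone gives about 1 in 20. The total count of NAP 6 was 20.98 M, against 16.6 to 18.1 M. For single genes the values in CPM were Wtip at 17.9 in NAP 6 (others up to 10.4), Bax at 143.9 in control 1 (up to 105), Il1rn at 346 in NAP 1 (up to 274), ND3 at 26.8 in NAP 1 (up to 11.97), Tm7sf2 at 53.7 in NAP 3 (up to 35.02), Nr1d2 at 65.6 in NAP 5 (up to 50.5) and Slc5a1 at 363 in NAP 1 (up to 230). Egfl7 was at 0.299 in NAP 2, below the other NAP libraries at 1.01 or more. L1cam was at 185 in control 1 and 139 in NAP 6, above the others of each group at up to 115 and 77.9. Krt4 was at 71.9 and Timp3 at 106 in control 1, against up to 10.2 and 10.8 in the other controls. F3 was at 457 and Cd68 at 11.9 in control 3, and Fn1 was at 25.5 in control 4 against up to 4.89. The brush border score of NAP 6 was −0.18, against 0.12 to 0.25 in the other NAP libraries.

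The first pattern is the 315 called genes. Among 100 of the 462 splits of the 11 libraries, 3 gave as many genes, with the real split counted among the 100 here and below. With 1 surrogate variable each, 2 of 100 did (3083 in the real split, 4543 in the highest other). Both counts were below the limit of 5 of 100. Chance is thereby argued against but not excluded, as other splits called more genes and only a part of the splits was drawn. Another split called 2463, several times the real count, which points to a structure of the samples. That split set controls 2 and 5 with NAP 2, 4 and 5 against the rest, and one that set controls 1 and 4 with NAP 1, 3 and 6 apart called 499. With the crypt to colonocyte score as a covariate the real split called 3213 genes and the highest other split 65. The real split was thus the 1 of 100 as large, which argues against position on that axis as the whole cause. With each library's GC trend removed 30 genes were called, and 3 of 100 splits gave as many (highest 2967), below the limit of 5 of 100. By genes at an unadjusted p below 0.05 (2433), 6 of 100 were as large, so the test does not decide whether that trend is the whole cause. Of 278 called genes with a GC value 27 kept their call. Their median change in log2 went from 0.94 ± 0.38 to 0.73 ± 0.44 (SD across genes) and their median SE from 0.20 to 0.18. With length removed too the change was 0.64 ± 0.44 and edgeR called 0 genes (2380 at an unadjusted p below 0.05), and splits were not counted for that fit. What stays open is how much of the difference comes from NAP and how much from composition, RNA quality or handling, as a hypothesis that NAP may change these genes has no second batch to be tested on.

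The second pattern is the 15 called lists. Of 100 splits, 55 called as many lists and the highest called 29, so chance could account for that number. With the crypt to colonocyte score as a covariate 11 lists were called, 49 of 100 splits gave as many and the highest gave 18. Taken by itself, no called list was rare among splits: the clock list came closest, with a p as small in 8 of 100, against 21 of 100 for cytosolic ribosomal proteins and 36 of 100 for ribosome biogenesis. Genes in a list move together between libraries, which the preset correlation of 0.01 understates, and the estimated correlation left 0 calls.

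The third pattern is the larger mitochondrial share after NAP. COX1 by itself is argued against: without it the share was 1.69 ± 0.23% in controls and 2.64 ± 0.26% after NAP (exact permutation p = 0.00216, the smallest possible), and without the ribosomal RNA genes as well it was 1.40 ± 0.17% and 1.88 ± 0.35%, with overlap (exact permutation p = 0.0281). Colonocyte content as the whole cause is argued against too, since with the colonocyte score as a covariate the difference was 2.40 percentage points, from 2.79 without it. For the 12 protein-coding genes, the GC trend is a candidate explanation: with it removed their median log2 fold change went from 0.44 ± 0.36 to 0.0563 ± 0.39 (SD), those positive from 12 to 7, and the adjusted p of their list from 0.00415 to 0.420, though only 1.37% of genes have a GC content as low. A difference in mitochondrial RNA content caused by NAP stays open.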

How the results depend on the processing

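Of the settings named below, the pair of controls left out or added together, the GC, length, surrogate variable and crypt to colonocyte fits and the fit without the mitochondrial chromosome were chosen after seeing the data. Against 156 genes higher and 159 lower, the counts were within 1.5 times under size factors of DESeq2, upper-quartile scaling, 2 other filters, non-robust dispersion, limma voom, log2(FPKM + 1), log2(FPKM + 0.1), length removed and the mitochondrial chromosome left out. They were 22 and 19 by library size alone (where the median of all genes was −0.14, against −0.07), 56 and 33 with no filter (more genes tested), 838 and 832 with DESeq2's Wald test, 2058 and 2405 with voom quality weights, 79 and 63 with an absolute log2 fold change above 1, 368 and 428 with that and an unadjusted p below 0.05, 679 and 801 at an adjusted p below 0.1, and 1 and 1 with log2(FPKM + 1) and no filter. Leaving out 1 library each gave 0 to 411 higher and 0 to 435 lower. It gave 0 and 0 in edgeR without control 1, 2 or 5 or NAP 2, 4 or 5 (2614 to 3311 genes at an unadjusted p below 0.05), 96 and 62 without control 3, 130 and 306 without control 4, 411 and 403 without NAP 1, 355 and 435 without NAP 3, and 80 and 32 without NAP 6. With the replicate number as a block, NAP 6 left out, edgeR called 0 higher and 0 lower (2871 genes at an unadjusted p below 0.05), and 80 and 32 with no block. Whether the numbers pair the libraries was not tested and stays open. The correlations of deviations for numbers 1 to 5 were 0.42, 0.34, −0.07, −0.30 and 0.30, and 2 of 5 controls correlated best with their own number. Controls 2 and 5 left out gave 420 and 404, and added into 1 library 0 and 0 (edgeR, 3241 at an unadjusted p below 0.05). The GC trend removed gave 22 and 8, GC and length removed 0 and 0 (2380 at an unadjusted p below 0.05), 1 surrogate variable 1613 and 1470, and the crypt to colonocyte covariate 1622 and 1591. The last pair kept all 315 genes. Of the 315 genes, those tested under a setting (278 to 315) kept their sign, which says little, as they were selected for their difference in these same libraries. Where no construction shows it, the cause was not tested. Against 8 lists higher and 7 lower, camera with an estimated correlation and fry gave 0 and 0 (0 and 11 lists at an unadjusted p below 0.05). Leaving out 1 library gave 3 to 8 higher and 5 to 11 lower: 4 higher without control 1, 3 higher without control 4, and 11 lower without control 2 or 5. Controls 2 and 5 left out gave 13 and 15, added together 11 lower, and the crypt to colonocyte covariate 5 higher. For single named genes 682 values lost their call, 406 gained one and 4093 kept their side; for lists these were 79, 46 and 1116. At these depths 25 of 100 simulated genes changed by 1 in log2 were recovered.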

Other observations

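The tests of clock phase and of spread between libraries given here were chosen after the result was seen. Several called genes fell outside the 15 lists. Jund, an AP-1 transcription factor gene, fell 1.94-fold, from 672 ± 160 to 345 ± 73.5 CPM (SD, n = 5 and 6), and Bax, the pro-apoptotic effector, fell 1.93-fold. Xiap, an inhibitor of caspases, rose 1.87-fold to 161 ± 28.2 CPM, and Pmaip1, a pro-apoptotic p53 target named after its values were seen, rose 2.96-fold to 204 ± 108 CPM. The apoptosis list was not called (13 of 21 positive, camera adjusted p = 0.259). Tnfaip3, a brake on NF-kB signalling, rose 1.62-fold, while its NF-kB list was not called (13 of 22 positive, camera adjusted p = 0.120). Il1rn, the interleukin-1 receptor antagonist gene, rose 1.78-fold. Hes1, a Notch target, fell 1.48-fold, Tubg1 fell 1.92-fold, and the zinc transporter gene Slc39a14, the integrin gene Itgb6, the p53 target Trp53inp1 and the chaperone gene Dnajb9 rose 1.89-fold, 1.87-fold, 2.08-fold and 1.63-fold.

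In the list of oxidative phosphorylation genes 29 of 32 were negative (median −0.25), against 12 of 12 positive for mitochondrially encoded genes (7 of 12 with the GC trend removed), but the first list was not called (camera adjusted p = 0.163) and the difference between the lists was not tested. Uqcrc1 had 631 ± 332 and 344 ± 48.2 CPM and Ndufa2 85.8 ± 36.4 and 48.9 ± 18.3 CPM, neither past the test. The oxidative phosphorylation score was high in controls 2 and 5 alone, at 0.89 and 0.84. Control 3 was at 0.03, and controls 1 and 4, at −0.49 and −0.78, lay below the NAP libraries at −0.22 to 0.08. Uqcrc1 had 1029 and 950 CPM in controls 2 and 5 and 312 to 463 CPM in the others, against 287 to 420 CPM after NAP. The lower values of this list thus rest largely on those 2 controls. In the clock list the 4 genes of the Arntl arm (Arntl, Npas2, Clock, Nfil3) had a median log2 fold change of 0.14, with 3 positive, and 8 genes of the Per and Nr1d1 arm had 0.71, with 7 positive. Both arms were named after their values were seen, and a test of a shift in clock phase on them, whose outcome counted against such a shift, was set aside afterwards as too weak to decide.

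Of the 6 tested genes in the squamous list, which was not called, Lor and Krt4 were high in part of the controls, while Perp, Sfn and Dsg3 had log2 fold changes of 0.42, −0.22 and 0.29 and Krt15 was below 1 CPM on average in both groups. Lor was at 72.3 CPM in control 1 and 119 CPM in control 4, and from 1.00 to 9.09 CPM in the other controls, with 0 to 7.32 CPM in the NAP libraries. Krt4 was at 71.9 and 10.2 CPM in controls 1 and 4.

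The NAP libraries lay closer to their mean than the controls did, at a mean distance of 0.55 against 0.74 in log2 CPM. The hypothesis that spread is smaller after NAP may hold, but the two-sided exact permutation p was 0.0671, and with 5 controls it cannot be told apart from chance. The rule for reading this test was changed after that p was seen: by the first rule a p of 0.05 or more counted against the hypothesis.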
